A study of Mus musculus with 27 samples.

How the data were processed

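Small RNA was sequenced from 27 samples of C57BL/6 mice: SCN, hypothalamus and cortex tissue (2 libraries each), an SCN time course (11 libraries, 1 per time from ZT2 to ZT42), AVP, VIP and CCK neurons of the SCN (2 each), and CTRL and LP samples at CT18 (2 each). Per the labels' protocols, tissue was frozen in liquid nitrogen, total RNA was taken with Trizol, and libraries followed Illumina protocols. The labels do not say how the AVP, VIP and CCK neurons were collected. Bowtie and the mouse genome build GRCm38 (mm10) are named, without a version or role for Bowtie, per the submitters' processing notes. Samples were grouped by the labels alone, and 0 columns were left without a group.

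The deposited values are a normalized signal per mature miRNA, reads scaled to a total of 1e+07 per library and listed as whole numbers, as the deposited values themselves show: totals were 10004170 to 10021510. In every library 100% of the values were whole multiples of 1 step, rounded down, with steps of 1.95 to 21.3, so the number of reads behind each value was recovered. On 6 simulated libraries this recovery gave at least 99.8% of the values correctly. Levels in CPM are the deposited value divided by 10. Totals exceeded 1e+07 by 4170 to 21510, and the cause was not tested. miR-486-5p and miR-3107-5p differ by at most 1.10% in any library and are reported as an uncertain pair. The excess lay close to the level of miR-3107-5p in AVP replicate 1 (2151 against 2162.2 CPM) and above it in cortex replicate 1 (417 against 130.4). Other entries were equal too: miR-199a-3p and miR-199b-3p had the same means in the CT18 controls and in the ZT18 and ZT42 libraries. Such entries were tested as separate miRNAs. The series names 844 miRNAs, of which 736 (87.2%) matched 1 precursor gene of GENCODE M21 (GRCm38). miRNAs made from several copies were given no position.

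Depth was taken as the recovered reads, 469808 to 5133920 per library. A floor of 3 reads set the level that 0 reads allow, 0.837 to 1.54 CPM in tissue, 0.585 to 1.15 in the time course, 1.07 to 6.39 in neurons and 1.02 to 1.70 at CT18. Bounds on folds used 3 reads over all libraries of the group. Replicates correlated across miRNAs on the log2 scale with r from 0.935 (AVP neurons) to 0.997 (cortex), where miRNAs are not independent replicates. Differences between replicates exceeded counting error in every group, by a chi-square per degree of freedom of 14.9 (CCK neurons) to 652 (VIP neurons).

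The plan named edgeR for counts and limma-trend for normalized values. As the files hold normalized values, limma-trend (limma 3.58.1, R 4.3.3) was used on log2(value + 1), with 1 model for the 3 tissues, 1 for the 3 neuron types, 1 for CT18 and 1 for the time course. Tested miRNAs had a value of at least 100 (10 CPM) in at least 2 libraries of the model, or at least 3 for the time course. That minimum was set after the format was seen and before any model was fitted. p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05, and tests were two-sided. Rhythm was tested with cosine and sine terms of a 24 h period together, on 8 residual degrees of freedom. Fold changes in the text are ratios of mean CPM, and log2 fold changes are those of the model. No miRNA was tested between parts, since each part may be its own batch.

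The comparisons, the tests, the miRNA lists, the naming rule and most of the other settings tried were fixed before the data were examined. Named were, per comparison, the 10 largest rises and 10 largest falls among miRNAs past the threshold whose replicates did not overlap and whose mean was at least 50 CPM in the higher group (20 smallest adjusted p for the rhythm). Where fewer than 5 passed, the 5 smallest p were given as values. The 10 most abundant miRNAs of each kind of library and up to 4 members of each list, those with the smallest p, were named too. Other miRNAs were chosen after their values were seen. The 19 lists, with members found out of members listed, were neuronal brain miRNAs (23 of 24), hypothalamic and endocrine miRNAs (12 of 13), clock-linked miRNAs (37 of 37), activity-regulated miRNAs (14 of 14), the miR-183, miR-96 and miR-182 sensory cluster (4 of 6), the miR-379 to miR-410 imprinted cluster (69 of 71), the miR-127 and miR-136 imprinted cluster (22 of 23), the let-7 family (11 of 11), the miR-30 family (5 of 6), the miR-29 family (7 of 7), the miR-17 to miR-92a and paralogue clusters (16 of 17), Htr2c-intron miRNAs (9 of 11), oligodendrocyte miRNAs (6 of 9), microglia and leukocyte miRNAs (9 of 9), erythrocyte miRNAs (5 of 5), vascular miRNAs (8 of 8), choroid plexus and ciliated-cell miRNAs (9 of 11), muscle miRNAs (6 of 6), and liver and gut miRNAs (6 of 6). Lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation.

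Settings chosen then were quantile normalization, no filter (a value of at least 1), a filter of 100 CPM, a pseudocount of 10, the replicate number as a block, a model of only the 4 libraries of a pair, other rhythm models and leaving out each library. Added after seeing the data were median-ratio scaling, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the time course without ZT2 and ZT6, and only miRNAs at 100 or more in all 6 neuron libraries. Each model was tested on simulated data with 200 changed miRNAs in each of 5 runs, and 0.69% to 2.23% of unchanged miRNAs passed. Noise was drawn independently for each miRNA. With so many changed at once, the recovery rates may overstate those for a response of few miRNAs. Times of the time course were permuted 100 times. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Raw reads and sequences were not used here.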

Results

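Mature miRNAs were measured by small-RNA sequencing in 27 libraries from C57BL/6 mice, in 4 parts. The suprachiasmatic nucleus (SCN), the brain's central circadian clock, was sequenced beside hypothalamus and cortex, with 2 libraries for each tissue. A time course of the SCN held 1 library at each of 11 times, every 4 h from ZT2 to ZT42 (zeitgeber time, hours counted from lights on). AVP, VIP and CCK neurons of the SCN, named for the neuropeptides vasopressin, vasoactive intestinal peptide and cholecystokinin, gave 2 libraries each. At CT18 (circadian time 18 h), 2 libraries named CTRL stood beside 2 named LP. The labels do not spell out LP, and the series description speaks of miRNAs that respond to light.

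Each library held 469808 to 5133920 miRNA reads: 2245915 and 3585377 for the SCN, 2220098 and 2282921 for hypothalamus, 1946998 and 2523334 for cortex, and 2604731 (ZT10) to 5133920 (ZT26) along the time course. AVP neurons gave 537185 and 908476 reads, VIP neurons 2786568 and 2812318 and CCK neurons 469808 and 487360, while the CTRL libraries held 1777244 and 1931919 and the LP libraries 1766808 and 2939619. The tissue libraries listed 582 to 634 miRNAs above 0 and the neuron libraries 215 to 312. A miRNA at 0 reads in 1 library could still reach 0.585 to 6.39 CPM (3 reads). These floors cover counting error only.

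A few miRNAs made up most of every library, the 10 most abundant holding 56.6% to 81.1% of the reads. In the SCN these were led by miR-125b-5p (13.3% ± 0.737, mean ± SD, n = 2) and miR-125a-5p (12.4% ± 0.499), both homologues of worm lin-4, with miR-127-3p (12.2% ± 2.12) from the imprinted Dlk1-Dio3 region and miR-26a-5p (10.03% ± 0.149). In hypothalamus miR-26a-5p came first (13.0% ± 0.253), ahead of miR-127-3p (9.99% ± 0.453), miR-99a-5p (9.05% ± 0.562) and miR-7a-5p (6.35% ± 0.0497). Cortex was led by miR-26a-5p (16.3% ± 0.461), miR-99a-5p (7.56% ± 0.194), and the neuronal miR-128-3p (6.43% ± 0.0514) and miR-124-3p (6.14% ± 0.356). Along the time course miR-125b-5p held 14% ± 1.66 and miR-125a-5p 13.9% ± 1.95 (n = 11). In the neuron libraries miR-125a-5p held 25.1% ± 2.89 in AVP, 33.7% ± 8.17 in VIP and 18.4% ± 0.0290 in CCK neurons, and miR-127-3p 24.01% ± 0.605, 20.4% ± 3.96 and 15.0% ± 0.215. CTRL libraries were led by miR-26a-5p (15.9% ± 0.123) and miR-125b-5p (14.6% ± 0.0619), as were LP libraries (15.3% ± 1.54 and 13.5% ± 2.15). miR-127 lies on chromosome 12, 109592846 to 109592915 (GRCm38), antisense to an exon of Rtl1, and miR-125a on chromosome 17, 17830812 to 17830879, in an exon of Spaca6.

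The SCN was set against hypothalamus to find the miRNAs that mark the clock nucleus within its surroundings. miR-200c-3p, an epithelial miRNA that represses Zeb1 and Zeb2, stood at 87.9 ± 11.5 against 12 ± 5.94 CPM (levels are the deposited value divided by 10, mean ± SD, n = 2 libraries per group for every tissue value), 7.32-fold higher in the SCN (log2 fold change 2.95 ± 0.39 SE, limma adjusted p = 0.00013). Its relative miR-200b-3p rose 5.83-fold (298 ± 37.5 against 51.1 ± 17) and miR-375-3p, best known from pancreatic islets and pituitary, rose 3.78-fold (90.5 ± 2.97 against 24 ± 2.33). Far more abundant, miR-125a-5p rose 3.61-fold (124059 ± 4989.8 against 34401 ± 1592) and miR-149-5p 3.68-fold (7285 ± 1068 against 1982 ± 88.5). The sensory-organ miRNAs miR-182-5p and miR-183-5p rose 3.27-fold and 3.06-fold, the latter to 529 ± 49.6 against 173 ± 30.5. Also higher in the SCN were miR-1249-3p (4.95-fold), miR-455-3p (4.62-fold), miR-760-3p (4.05-fold), miR-1224-5p (3.86-fold) and miR-3099-3p (3.73-fold).

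Among the miRNAs lower in the SCN than in hypothalamus, the red-cell miRNAs miR-144-3p and miR-451a fell 41.9-fold (2.90 ± 0.283 against 121 ± 36.1) and 8.26-fold (29.7 ± 5.80 against 245 ± 136), and the muscle miRNA miR-1a-3p fell 7.78-fold (34.8 ± 15 against 271 ± 4.10). Of 4 erythrocyte miRNAs tested 3 fell, but miR-486-5p rose, with 544 and 453.8 CPM in the SCN libraries against 291.4 and 373.6 in hypothalamus. Erythrocyte miRNAs together held 541 ± 68.4 CPM in the SCN and 725 ± 242 in hypothalamus. The oligodendrocyte miRNAs miR-219-5p and miR-338-3p fell 21.6-fold (5.40 ± 2.97 against 117 ± 48.9) and 5.43-fold (452 ± 91.6 against 2452 ± 289). Smooth-muscle miR-143-3p fell 3.38-fold (2074 ± 158 against 7008 ± 539) and endothelial miR-126-5p 4.48-fold, while miR-21a-5p fell 6.40-fold (205 ± 21.6 against 1312 ± 141). Of neuronal miRNAs, miR-137-3p fell 5.69-fold (41.1 ± 13.1 against 234 ± 20.9), miR-135a-5p 4.63-fold and miR-9-5p 2.42-fold. miR-101a-3p, miR-101b-3p and miR-450a-5p fell 5.85-fold, 5.62-fold and 5.34-fold. miR-7a-5p, abundant in hypothalamus, was 1.69-fold lower in the SCN (37626 ± 1996 against 63466 ± 497). miR-96-5p, the third member of the sensory cluster, rose 1.53-fold, a call lost without SCN replicate 1 or 2 or hypothalamus replicate 1. miR-200c lies on chromosome 6, 124718322 to 124718390, miR-375 on chromosome 1, 74900658 to 74900721, and miR-144 on chromosome 11, 78073005 to 78073070 (GRCm38).

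Of 378 miRNAs tested between SCN and hypothalamus, 268 passed an adjusted p of 0.05 in limma, 106 higher and 162 lower in the SCN, and 57 of the rises and 110 of the falls exceeded 2-fold. Both SCN libraries lay on 1 side of both hypothalamus libraries for 330 miRNAs, where chance gives 2 of the 6 orders of 2 against 2 libraries. Median-ratio scaling placed the median miRNA 0.26 higher on the log2 scale (shift −0.26 in the deposited scaling), and the split moved to 128 higher and 134 lower with it, 126 and 138 after quantile normalization, 134 and 138 with edgeR and 122 and 118 with DESeq2. Leaving out any 1 library gave 215 to 243 calls. The labels do not say whether replicates were separate animals, so p-values here and in the other comparisons measure the spread between these libraries.

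Among the fixed lists, members that rose, fell and did not pass between SCN and hypothalamus numbered 6, 15 and 2 for neuronal brain miRNAs, 5, 3 and 2 for hypothalamic and endocrine miRNAs, 5, 18 and 11 for clock-linked miRNAs, 4, 3 and 5 for activity-regulated miRNAs, 3, 0 and 0 for the miR-183, miR-96 and miR-182 sensory cluster, and 10, 18 and 16 for the miR-379 to miR-410 imprinted cluster. The counts were 7, 6 and 5 for the miR-127 and miR-136 imprinted cluster, 5, 4 and 0 for the let-7 family, 0, 3 and 2 for the miR-30 family, 0, 3 and 1 for the miR-29 family, 1, 6 and 1 for the miR-17 to miR-92a and paralogue clusters, 0, 1 and 4 for Htr2c-intron miRNAs, and 0, 4 and 0 for oligodendrocyte miRNAs. They were 2, 3 and 0 for microglia and leukocyte miRNAs, 1, 3 and 0 for erythrocyte miRNAs, 0, 8 and 0 for vascular miRNAs, 3, 1 and 2 for choroid plexus and ciliated-cell miRNAs, 0, 2 and 0 for muscle miRNAs, and 0, 2 and 1 for liver and gut miRNAs. Adjusted over the list alone, every count stayed as given. All 8 vascular miRNAs were lower in the SCN, among them miR-126-3p (2.24-fold) and miR-145a-3p (3.30-fold), with a camera adjusted p of 0.035 for the list (adjusted p = 0.67 with an estimated correlation). Within the let-7 family 5 members rose and let-7g-5p was among the 4 that fell (1.77-fold). miR-30a-5p and miR-30e-5p fell 2.43-fold and 3.12-fold, miR-29c-3p 4.11-fold and miR-20a-5p 4.66-fold, while miR-92a-3p rose 1.76-fold. In the imprinted clusters miR-433-3p and miR-770-3p rose 2.57-fold and 3.31-fold, and miR-369-3p and miR-136-3p fell 3.26-fold and 3.59-fold. The median of the miR-127 and miR-136 imprinted cluster was −0.12 on the log2 scale and 0.14 with median-ratio scaling, and its camera direction was up.

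**Figure D1:**
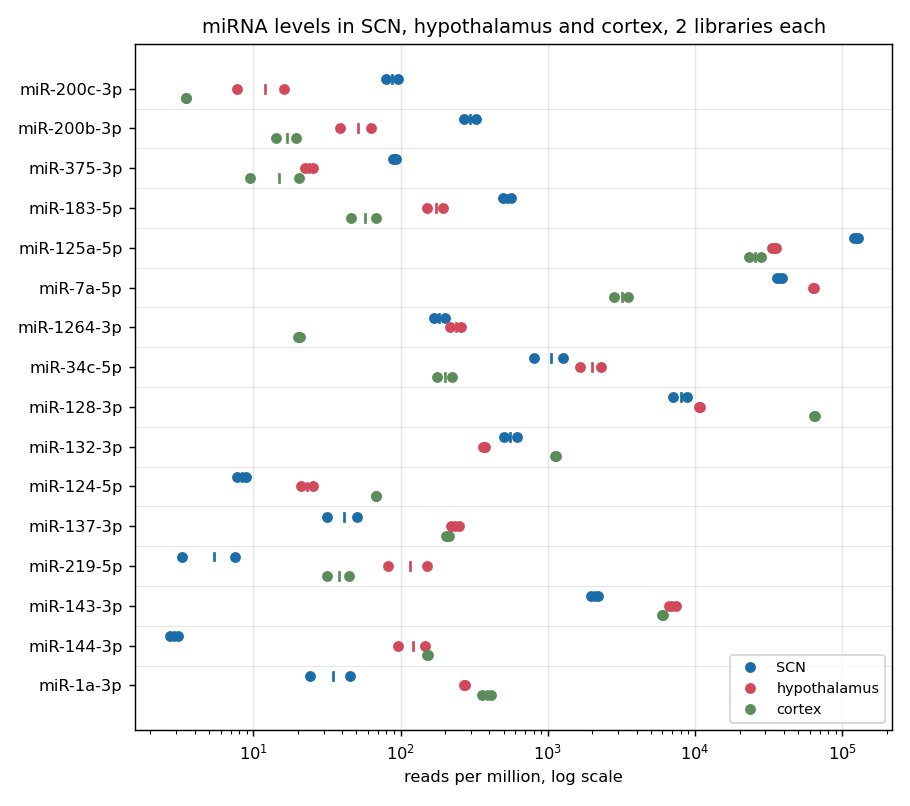
Level of 16 miRNAs in CPM (logarithmic axis) in SCN, hypothalamus and cortex, 1 dot per library and a tick at each mean. miR-200c-3p lies highest in the SCN (87.9 ± 11.5), miR-7a-5p lies at 63466 ± 497 in hypothalamus against 3169 ± 481 in cortex, and miR-144-3p is lowest in the SCN (2.9 ± 0.283).

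Against cortex the SCN differed more widely. miR-298-5p, from the imprinted Gnas region, rose 38.5-fold (2947 ± 352 against 76.6 ± 2.19, log2 fold change 5.26 ± 0.12 SE, limma adjusted p = 3.2e-09). The hypothalamic miR-7 family was high in the SCN, with miR-7a-5p at 37626 ± 1996 against 3169 ± 481 (11.9-fold), miR-7b-5p up 7.71-fold and miR-7a-2-3p up 33.1-fold (129 ± 14.4 against 3.90 ± 1.70). miR-34b-3p, a miRNA of multiciliated cells, rose 34-fold (213 ± 96.9 against 6.25 ± 2.76), and miR-204-5p, abundant in choroid plexus and retinal pigment epithelium, rose 7.16-fold (7478 ± 611 against 1045 ± 79.8). miR-200c-3p rose 25.1-fold, miR-200b-3p 17.7-fold, miR-182-5p 12.1-fold and miR-183-5p 9.30-fold. miR-1264-3p, from an intron of the serotonin receptor gene Htr2c, rose 9.03-fold (183 ± 22.4 against 20.3 ± 0.424) while its neighbour miR-448-5p, with 3 reads in cortex, stood at 15.6 ± 1.20 against 0.600 ± 0.141. miR-3099-3p, miR-760-3p and miR-224-5p rose 35.5-fold, 28.2-fold and 18-fold, and miR-770-3p and miR-770-5p, from the Dlk1-Dio3 region, 31.3-fold and 24.7-fold.

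Cortex held more of several neuronal miRNAs. miR-128-3p fell 8.08-fold in the SCN (7958 ± 1277 against 64285 ± 514), miR-128-2-5p, made from an intron of Arpp21, 6.38-fold, miR-124-5p 8.19-fold (8.35 ± 0.778 against 68.4 ± 0.141), miR-218-5p 5.90-fold, miR-138-5p 5.47-fold and miR-9-5p 5.48-fold. miR-144-3p fell 52.7-fold (2.90 ± 0.283 against 153 ± 1.91), miR-451a 8.03-fold, miR-1a-3p 11-fold (34.8 ± 15 against 383 ± 35.8) and miR-34a-5p 11.4-fold. Red-cell miR-486-5p went the other way, with 544 and 453.8 CPM in the SCN libraries against 131.2 and 201.4 in cortex. Erythrocyte miRNAs together held 541 ± 68.4 CPM in the SCN and 581 ± 90.2 in cortex. miR-101a-3p and miR-101b-3p fell 8.22-fold and 6.01-fold. limma passed 303 of 378 miRNAs, 156 higher and 147 lower in the SCN, with 119 rises and 109 falls beyond 2-fold. The groups did not overlap for 341 miRNAs. The split was 158 and 146 with edgeR and 147 and 142 with DESeq2, but 139 and 158 with quantile normalization and 146 and 157 with median-ratio scaling, so the side with more calls turned with the scaling. The scaling shift was 0.16 on the log2 scale, and leaving out 1 library gave 276 to 289 calls. Without SCN replicate 1 the side with more calls turned as well, to 138 higher and 146 lower.

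By list, SCN against cortex gave rises, falls and members that did not pass of 6, 16 and 1 for neuronal brain miRNAs, 8, 1 and 1 for hypothalamic and endocrine miRNAs, 6, 24 and 4 for clock-linked miRNAs, 3, 9 and 0 for activity-regulated miRNAs, 3, 0 and 0 for the miR-183, miR-96 and miR-182 sensory cluster, and 16, 14 and 14 for the miR-379 to miR-410 imprinted cluster. Further counts were 9, 5 and 4 for the miR-127 and miR-136 imprinted cluster, 3, 4 and 2 for the let-7 family, 0, 4 and 1 for the miR-30 family, 0, 3 and 1 for the miR-29 family, 1, 5 and 2 for the miR-17 to miR-92a and paralogue clusters, 5, 0 and 0 for Htr2c-intron miRNAs, and 1, 2 and 1 for oligodendrocyte miRNAs. The remaining lists gave 2, 3 and 0 for microglia and leukocyte miRNAs, 1, 3 and 0 for erythrocyte miRNAs, 0, 7 and 1 for vascular miRNAs, 6, 0 and 0 for choroid plexus and ciliated-cell miRNAs, 0, 2 and 0 for muscle miRNAs, and 1, 2 and 0 for liver and gut miRNAs. Adjusted over the list alone, 7 clock-linked miRNAs rose and 24 fell, and the other lists kept their counts. camera placed 6 lists past its threshold, and none of them passed with an estimated correlation. Hypothalamic and endocrine miRNAs (adjusted p = 0.019, limma's camera; adjusted p = 0.47 with an estimated correlation) and choroid plexus and ciliated-cell miRNAs (0.025 and 0.35) were higher in the SCN. Neuronal brain miRNAs (0.032 and 0.42), clock-linked miRNAs (0.018 and 0.35), the miR-30 family (0.032 and 0.47) and vascular miRNAs (0.025 and 0.35) were lower. Members behind them included miR-30a-5p and miR-30e-5p, down 4.88-fold and 4.66-fold, miR-126-5p and miR-143-3p, down 5.60-fold and 2.89-fold, and miR-24-3p and miR-27b-3p, down 3.78-fold and 3.33-fold. miR-29a-3p and miR-29c-3p fell 2.33-fold and 4.26-fold, miR-21a-5p 5.18-fold and miR-219-5p 7.09-fold, while miR-122-5p rose 3.94-fold. In the miR-379 to miR-410 imprinted cluster miR-666-5p rose 7.96-fold, its median was −0.03 and its camera direction was up.

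Hypothalamus against cortex gave the reference pair of regions. miR-7a-5p rose 20.03-fold (63466 ± 497 against 3169 ± 481, log2 fold change 4.33 ± 0.10 SE, limma adjusted p = 3.7e-09) and miR-7b-5p 10.8-fold. miR-216a-5p rose 34.4-fold (70.6 ± 27.2 against 2.05 ± 1.34), miR-298-5p 19.1-fold and miR-296-3p, from the same Gnas region, 6.14-fold. miR-34b-3p and miR-34c-5p rose 14.2-fold and 9.95-fold (1988 ± 457 against 199.8 ± 32.6 for the second), and miR-204-5p 5.01-fold. Of the Htr2c intron, miR-1264-3p rose 11.7-fold (237 ± 27.9 against 20.3 ± 0.424) and miR-448-5p stood at 19.9 ± 3.96 against 0.600 ± 0.141. miR-770-3p and miR-770-5p rose 9.45-fold and 8.50-fold. Cortex held more miR-128-3p (10696 ± 203 against 64285 ± 514, 6.01-fold lower in hypothalamus), miR-128-1-5p (14.2-fold), miR-128-2-5p (7.06-fold), miR-184-3p (4.30-fold), miR-129-1-3p (3.61-fold), miR-124-5p (2.94-fold), miR-221-3p (3.11-fold) and miR-221-5p (2.98-fold). The activity-induced miR-132-3p fell 3.06-fold (369 ± 10.6 against 1128 ± 5.94) and miR-132-5p 3.47-fold.

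limma passed 220 of 378 miRNAs between hypothalamus and cortex, 158 higher and 62 lower in hypothalamus, 97 and 26 of them beyond 2-fold, and the groups did not overlap for 317. The excess of rises differed with the scaling, whose shift was 0.42 on the log2 scale: median-ratio scaling gave 96 higher and 104 lower, quantile normalization 81 and 88, edgeR 124 and 87 and DESeq2 95 and 92. Leaving out 1 library gave 174 to 187 calls. let-7a-5p fell 1.24-fold, with a log2 change of 0 after quantile normalization, and its call was lost without hypothalamus replicate 1 or cortex replicate 1.

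By list, hypothalamus against cortex gave counts higher, lower and not passed of 4, 11 and 8 for neuronal brain miRNAs, 7, 0 and 3 for hypothalamic and endocrine miRNAs, 8, 13 and 13 for clock-linked miRNAs, 3, 9 and 0 for activity-regulated miRNAs, 3, 0 and 0 for the miR-183, miR-96 and miR-182 sensory cluster, and 20, 5 and 19 for the miR-379 to miR-410 imprinted cluster. Next came 10, 0 and 8 for the miR-127 and miR-136 imprinted cluster, 1, 4 and 4 for the let-7 family, 0, 4 and 1 for the miR-30 family, 0, 1 and 3 for the miR-29 family, 1, 0 and 7 for the miR-17 to miR-92a and paralogue clusters, 5, 0 and 0 for Htr2c-intron miRNAs, and 4, 0 and 0 for oligodendrocyte miRNAs. Last were 1, 2 and 2 for microglia and leukocyte miRNAs, 1, 0 and 3 for erythrocyte miRNAs, 1, 1 and 6 for vascular miRNAs, 5, 0 and 1 for choroid plexus and ciliated-cell miRNAs, 0, 0 and 2 for muscle miRNAs, and 1, 0 and 2 for liver and gut miRNAs. Adjusted over the list alone, 5 neuronal brain miRNAs rose, 5 members of the miR-30 family fell and no vascular miRNA fell, with the other counts as given. camera passed 8 lists, none of them with an estimated correlation. In camera a list is set against the other tested miRNAs, and all tested miRNAs had a median log2 change of 0.41 here. Activity-regulated miRNAs ranked lower than the others in hypothalamus (adjusted p = 0.00083 by limma's camera, adjusted p = 0.23 with an estimated correlation). So did neuronal brain miRNAs (0.0039 and 0.28), clock-linked miRNAs (0.0039 and 0.23), the miR-30 family (0.0049 and 0.45) and the let-7 family (0.026 and 0.59). The medians of these lists were −0.84, −0.12, −0.06, −0.45 and −0.21 in that order. Htr2c-intron miRNAs (0.019 and 0.28), choroid plexus and ciliated-cell miRNAs (0.026 and 0.28) and hypothalamic and endocrine miRNAs (0.026 and 0.59) were higher. All 4 oligodendrocyte miRNAs tested were higher in hypothalamus, with miR-338-3p up 2.04-fold (not passed after quantile normalization) and miR-219-2-3p up 3.17-fold. The median of the miR-379 to miR-410 imprinted cluster was 0.50, and 0.08 with median-ratio scaling, with miR-495-3p up 4.07-fold. Medians turned from positive to negative with median-ratio scaling in the miR-29 family (0.10 to −0.33, camera direction down), the miR-17 to miR-92a and paralogue clusters (0.32 to −0.10), microglia and leukocyte miRNAs (0.30 to −0.12, camera direction down), vascular miRNAs (0.14 to −0.28, camera direction down) and liver and gut miRNAs (0.21 to −0.21).

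The SCN time course was used to look for miRNAs with a 24 h rhythm. miR-370-3p, from an intron of Rian in the Dlk1-Dio3 region (chromosome 12, 109618258 to 109618336, GRCm38), gave the smallest p, with levels from 2605 CPM at ZT2 to 5129.6 at ZT38 and a fitted peak at 12.9 h (amplitude 0.38 ± 0.11 SE on the log2 scale, limma unadjusted p = 0.0077, n = 11). miR-7a-5p stood at 40337 at ZT2 and 26371 at ZT6, and between 9000.3 and 15906 from ZT10 on (amplitude 0.55 ± 0.19). At ZT26, 24 h after the first library, it stood at 15381, and its amplitude without ZT2 was 0.32. miR-7b-5p followed the same course (12429 at ZT2, 5220.1 at ZT26, amplitude 0.54 ± 0.19, and 0.30 without ZT2). let-7f-5p stood at 25929 at ZT2, 7613 at ZT14 and 19287 at ZT26 (amplitude 0.51 ± 0.18). The let-7 family together held 99109, 85628 and 87524 CPM at ZT2, ZT6 and ZT10. At ZT26, ZT30 and ZT34, 24 h later, it held 59187, 41902 and 38968 and so did not return to those levels. miR-125a-5p ran from 96276 at ZT2 to 159267 at ZT18 (amplitude 0.23 ± 0.08, and 0.15 without ZT2). miR-132-3p, a light-induced miRNA of the SCN, ranged from 222 to 620.0 (amplitude 0.16 ± 0.19), and miR-219-5p, linked to the clock through CLOCK, from 8.30 to 33.2 (amplitude 0.21 ± 0.32). The sensory cluster varied more, miR-183-5p from 21.5 to 206 and miR-96-5p from 8.20 to 81.

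None of the 357 miRNAs tested passed an adjusted p of 0.05 for a 24 h curve in limma (smallest adjusted p = 0.95), and 6 had an unadjusted p under 0.05. edgeR passed 0, with 13 under 0.05 unadjusted. Leaving out any 1 time gave 0 calls in limma, but the 6 became 27 without ZT26 and 27 without ZT30, 11 without ZT34, and 3 or fewer without ZT2, ZT6, ZT14 or ZT18. With 1 library per time, the spread at each time was not measured. In simulated data on 349 tested miRNAs, the same test recovered 8.05% of rhythms with a 1.5-fold range from trough to peak, 37.4% at 2-fold and 90.8% at 4-fold. Each simulated run held 200 rhythmic miRNAs, so these rates may overstate recovery where few are rhythmic. No list had a member past the threshold, adjusted over all miRNAs or adjusted over the list alone. The let-7 family passed camera for the sine term (adjusted p = 2.7e-06 with limma's camera; adjusted p = 0.99 with an estimated correlation), and vascular miRNAs for the cosine term (0.021 and 0.96). The smallest unadjusted limma p was 0.031 in the let-7 family, for let-7f-5p, and 0.096 in the vascular list, for miR-126-3p. let-7i-5p reached an unadjusted limma p of 0.057.

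**Figure D2:**
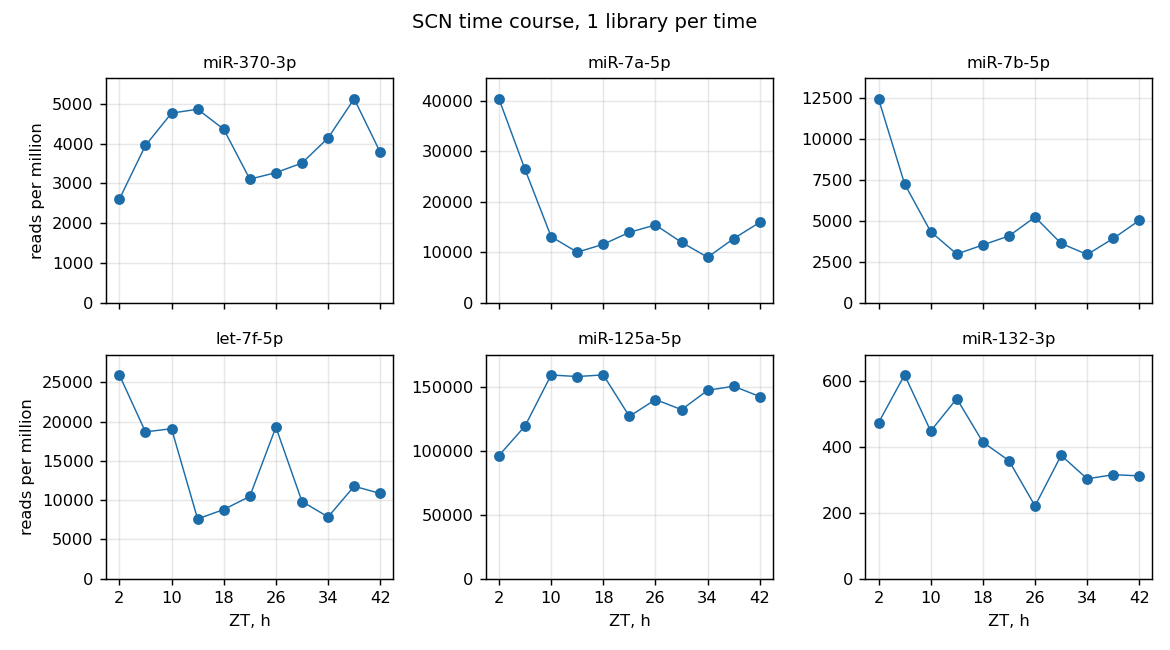
Level in CPM against zeitgeber time in h for 6 miRNAs of the SCN time course, 1 library per time. miR-7a-5p and miR-7b-5p are highest at ZT2 (40337 and 12429) and do not return to that level at ZT26, while miR-370-3p is lowest at ZT2 (2605).

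AVP, VIP and CCK neurons were compared to find miRNAs that differ between neuron types of the SCN. miR-204-5p, from an intron of Trpm3 (chromosome 19, 22750605 to 22750672, GRCm38), stood at 79 ± 3.68 in AVP and 8508 ± 1336 in VIP neurons, 108-fold lower in AVP (mean ± SD, n = 2 libraries per group for every neuron value, log2 fold change −6.74 ± 0.25 SE, limma adjusted p = 0.00046). Of 9 let-7 family members tested, 4 were lower in AVP, 1 was higher and 4 did not pass. Lower were let-7e-5p by 13.2-fold (1868 ± 10.7 against 24705 ± 3288), let-7a-5p by 5.38-fold, let-7f-5p by 4.98-fold and miR-98-5p by 18.3-fold. The neuronal miR-124-3p fell 4.06-fold (3029 ± 919.8 against 12288 ± 2247), miR-128-3p 44.7-fold and miR-342-3p 7.93-fold. miR-27b-3p rose 52-fold in AVP (6066 ± 764 against 117 ± 41.2) and miR-24-3p 5.23-fold. Of the miR-344 relatives, miR-344d-3p rose 206-fold (443 ± 80.5 against 2.15 ± 3.04, a call lost without AVP replicate 1 or 2) and miR-344-3p rose at least 204-fold (109 ± 59.3 against 0 reads, lost without AVP replicate 1). miR-183-5p rose at least 119-fold (63.9 ± 46.8 against 0 reads, not passed with edgeR).

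Within the miR-379 to miR-410 imprinted cluster of chromosome 12, neighbours moved in opposite directions between AVP and VIP. Unequal capture of single sequences in library preparation was not tested as a cause. miR-409-5p (chromosome 12, 109743158 to 109743236, GRCm38) rose 48.8-fold in AVP (15981 ± 1829 against 328 ± 27.9) and miR-485-3p 352-fold, whereas miR-329-3p (chromosome 12, 109713481 to 109713577) had 0 AVP reads against 1875 ± 838 in VIP, at least 904-fold lower (limma adjusted p = 0.0014). Lower bounds of this kind set 3 reads over the group's libraries in place of 0. miR-154-3p was at least 121-fold lower in AVP (251 ± 135 in VIP, not passed with DESeq2) and miR-376b-5p 12.7-fold lower. Also at 0 AVP reads were miR-365-3p (258 ± 44.1 in VIP, at least 124-fold lower), miR-1981-3p (at least 93.9-fold), miR-342-5p (144 ± 62.1, at least 69.6-fold), miR-135b-5p (at least 44.9-fold), endothelial miR-126-3p (55.9 ± 2.40, at least 26.9-fold) and miR-672-5p (at least 24.7-fold). The calls of miR-135b-5p and miR-126-3p were not made by edgeR. miR-92b-5p was at least 216-fold lower and miR-181c-5p 166-fold lower, with the first call lost without any 1 of the 4 libraries and the second without VIP replicate 1 or 2. Rises of miR-582-3p (125-fold) and miR-296-3p (70.3-fold) were lost without AVP replicate 1 or 2 and with median-ratio scaling, and that of miR-28a-3p (at least 103-fold) without VIP replicate 2 and with edgeR or DESeq2. miR-412-5p, with 3 reads in VIP, stood at 76.1 ± 23.3 against 0.50 ± 0.707, a call lost without AVP replicate 1 or 2. miR-132-3p fell 5.57-fold (436 ± 197 against 2429 ± 689), lost without VIP replicate 1, and miR-7a-5p did not pass (16738 ± 3897 against 10937 ± 1378).

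limma passed 100 of 305 miRNAs between AVP and VIP, 55 higher and 45 lower in AVP, 29 of them with 1 group at 0 reads. The groups did not overlap for 197. The side with more calls differed with the scaling, with a shift of 0.65 on the log2 scale: median-ratio scaling gave 35 higher and 62 lower, edgeR 27 and 48, and DESeq2 48 and 72. Without AVP replicate 1 the split was 32 and 44, without AVP replicate 2 33 and 63, and without VIP replicate 1 60 and 33. In simulated data on 301 tested miRNAs, 4.98% of 2-fold, 23.8% of 4-fold and 54.7% of 16-fold changes were recovered.

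By list, members higher, lower and not passed in AVP against VIP were 5, 5 and 12 for neuronal brain miRNAs, 0, 0 and 3 for hypothalamic and endocrine miRNAs, 8, 4 and 16 for clock-linked miRNAs, 3, 2 and 7 for activity-regulated miRNAs, 1, 0 and 0 for the miR-183, miR-96 and miR-182 sensory cluster, and 13, 5 and 23 for the miR-379 to miR-410 imprinted cluster. Then followed 4, 0 and 15 for the miR-127 and miR-136 imprinted cluster, 1, 4 and 4 for the let-7 family, 2, 0 and 3 for the miR-30 family, 0, 2 and 1 for the miR-29 family, 0, 0 and 5 for the miR-17 to miR-92a and paralogue clusters, and 0, 2 and 1 for Htr2c-intron miRNAs. Others were 0, 0 and 2 for oligodendrocyte miRNAs, 0, 1 and 2 for microglia and leukocyte miRNAs, 1, 1 and 1 for erythrocyte miRNAs, 0, 1 and 4 for vascular miRNAs, 0, 1 and 3 for choroid plexus and ciliated-cell miRNAs, and 0, 0 and 3 for liver and gut miRNAs. No muscle miRNA was tested. Adjusted over the list alone, 10 clock-linked miRNAs rose and 5 fell, 8 of the miR-379 to miR-410 imprinted cluster fell, 5 of the let-7 family fell, 3 of the miR-30 family rose, 3 Htr2c-intron miRNAs and 2 oligodendrocyte miRNAs fell, and choroid plexus and ciliated-cell miRNAs gave 1 rise and 2 falls, with the other lists as given. The let-7 family alone passed camera (adjusted p = 0.045 with limma's camera; adjusted p = 0.77 with an estimated correlation). The family median was −1.52, and −2.17 with median-ratio scaling. miR-29a-3p fell 2.80-fold, miR-30e-5p rose 3.34-fold (lost without AVP replicate 1 or 2), and miR-433-3p rose 2.92-fold (lost with median-ratio scaling). miR-1264-3p of the Htr2c intron had 0 AVP reads against 39.7 ± 0.212 in VIP, at least 19.1-fold lower. With median-ratio scaling the medians of hypothalamic and endocrine (0.52 to −0.13), clock-linked (0.56 to −0.03) and vascular miRNAs (0.49 to −0.15, camera direction down) changed sign.

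**Figure D3:**
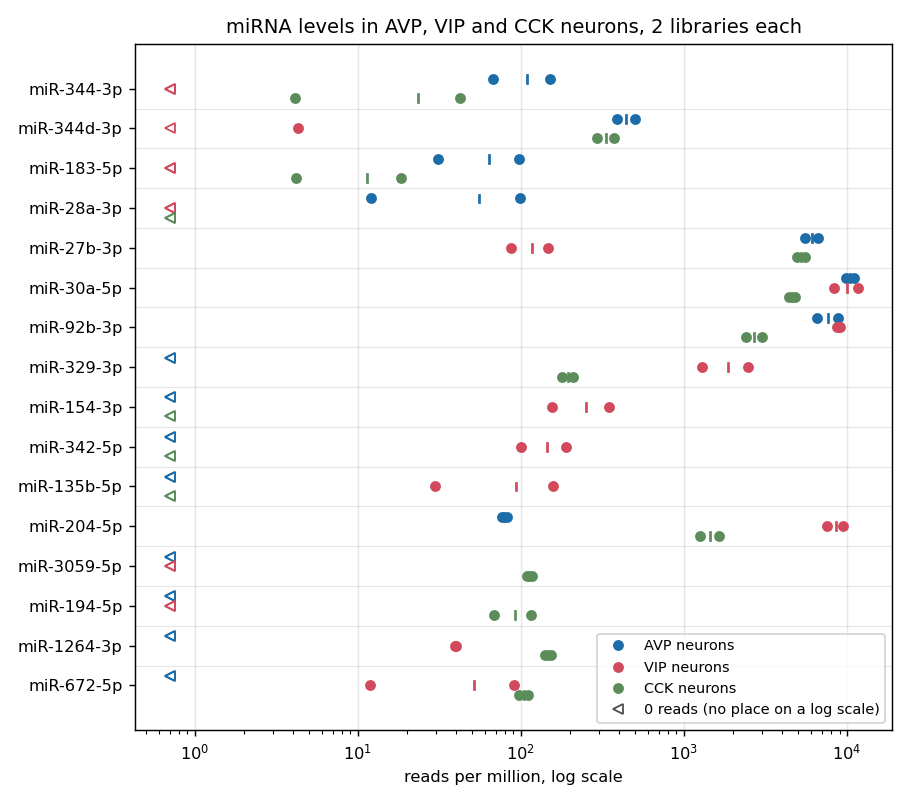
Level of 16 miRNAs in CPM (logarithmic axis) in AVP, VIP and CCK neurons, 1 dot per library, a tick at the mean where both libraries are above 0 and an open triangle at the left edge for 0 reads. miR-329-3p is at 0 reads in both AVP libraries and at 1875 ± 838 in VIP, and miR-27b-3p stands at 117 ± 41.2 in VIP against 6066 ± 764 in AVP.

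Of 9 let-7 family members, 7 were lower in AVP than in CCK neurons and 2 did not pass, with let-7e-5p down 8.66-fold (1868 ± 10.7 against 16179.5 ± 1430.3, log2 fold change −3.11 ± 0.16 SE, limma adjusted p = 0.0039), let-7a-5p 4.96-fold, let-7f-5p 3.86-fold and let-7d-5p 3.21-fold. miR-204-5p was 18.4-fold lower in AVP (79 ± 3.68 against 1451 ± 277), miR-124-3p 3.54-fold, miR-135a-5p 4.99-fold, miR-495-3p 4.55-fold and miR-125b-5p 2.95-fold. At 0 AVP reads were miR-329-3p (194 ± 21.3 in CCK, at least 93.4-fold lower), miR-1264-3p (147 ± 9.48, at least 71-fold; chromosome X, 147010601 to 147010686, GRCm38), miR-3059-5p (113 ± 5.94, at least 54.4-fold), the liver and gut miRNA miR-194-5p (91.6 ± 33.2, at least 44.1-fold), miR-672-5p (at least 50.3-fold), miR-1298-3p (at least 43.1-fold), miR-29b-3p (at least 35.5-fold), miR-130a-3p (at least 29-fold), miR-1188-5p (at least 25.9-fold), miR-1981-3p (at least 24.6-fold) and miR-137-3p (at least 21.2-fold). Higher in AVP were miR-92b-3p (7675 ± 1548 against 2703 ± 423, 2.84-fold), miR-30a-5p (10450.1 ± 777 against 4614 ± 285, 2.26-fold), miR-30d-5p (2.22-fold), and the near-identical pair miR-486-5p and miR-3107-5p (2.14-fold and 2.13-fold). miR-28a-3p and miR-433-5p had 0 CCK reads and were at least 17.7-fold and 14.2-fold higher in AVP.

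limma passed 51 of 305 miRNAs between AVP and CCK, 8 higher and 43 lower in AVP, 26 of them with 1 group at 0 reads, and the groups did not overlap for 177. Single libraries moved this count: 26 passed without AVP replicate 1, 69 without AVP replicate 2, and 0 without CCK replicate 1 or replicate 2 (54 and 49 at an unadjusted p under 0.05), so each call named for this pair was lost or untested without a CCK library. Without AVP replicate 1 the calls of miR-92b-3p, miR-30a-5p, miR-30d-5p, miR-486-5p, miR-3107-5p, miR-495-3p, miR-672-5p, miR-1298-3p, miR-130a-3p and miR-1188-5p were lost too, and without AVP replicate 2 those of miR-30a-5p, miR-486-5p and miR-3107-5p. edgeR did not pass miR-28a-3p, miR-433-5p, miR-3059-5p, miR-194-5p, miR-672-5p, miR-1298-3p, miR-29b-3p, miR-130a-3p, miR-1188-5p or miR-137-3p, and quantile normalization did not pass miR-124-3p or miR-433-5p. The scaling shift was −0.17. Median-ratio scaling gave 15 higher and 43 lower, quantile normalization 15 and 41, edgeR 7 and 21, and DESeq2 18 and 41. In simulated data on 295 tested miRNAs, 8.36% of 2-fold, 31.2% of 4-fold and 61.0% of 16-fold changes were recovered.

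By list, AVP against CCK gave members higher, lower and not passed of 0, 5 and 17 for neuronal brain miRNAs, 0, 1 and 2 for hypothalamic and endocrine miRNAs, 2, 3 and 23 for clock-linked miRNAs, 0, 1 and 11 for activity-regulated miRNAs, 0, 0 and 1 for the miR-183, miR-96 and miR-182 sensory cluster, and 0, 4 and 37 for the miR-379 to miR-410 imprinted cluster. Counts further on were 1, 0 and 18 for the miR-127 and miR-136 imprinted cluster, 0, 7 and 2 for the let-7 family, 2, 0 and 3 for the miR-30 family, 0, 1 and 2 for the miR-29 family, 0, 0 and 5 for the miR-17 to miR-92a and paralogue clusters, and 0, 2 and 1 for Htr2c-intron miRNAs. The rest were 0, 0 and 2 for oligodendrocyte miRNAs, 0, 1 and 2 for microglia and leukocyte miRNAs, 1, 0 and 2 for erythrocyte miRNAs, 0, 0 and 5 for vascular miRNAs, 0, 2 and 2 for choroid plexus and ciliated-cell miRNAs, and 0, 1 and 2 for liver and gut miRNAs. Adjusted over the list alone, 8 of the let-7 family, 2 vascular miRNAs and 2 liver and gut miRNAs fell and no member of the miR-127 and miR-136 imprinted cluster rose, with the other counts as given. The let-7 family passed camera (adjusted p = 0.00033 with limma's camera; adjusted p = 0.51 with an estimated correlation), with a median of −2.36, and −2.19 with median-ratio scaling. The clock-linked median was −0.10, and 0.07 with median-ratio scaling, with a camera direction of up. Activity-regulated miRNAs had a median of −0.43 and a camera direction of up.

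Between VIP and CCK neurons, miR-23b-3p and miR-27b-3p of 1 cluster moved in opposite directions. Whether the neurons or unequal capture of single sequences in library preparation set cluster neighbours apart here was not tested. miR-23b-3p rose 16.5-fold in VIP (1579 ± 167 against 95.6 ± 33.6), while miR-27b-3p of the same cluster (chromosome 13, 63300712 to 63300784, GRCm38) fell 44.8-fold (117 ± 41.2 against 5224 ± 397, log2 fold change −5.53 ± 0.31 SE, limma adjusted p = 0.003). miR-27a-3p fell 42.1-fold and miR-24-3p 4.18-fold. In the miR-379 to miR-410 imprinted cluster, miR-409-5p fell 31.4-fold (328 ± 27.9 against 10279 ± 52, limma adjusted p = 0.00055) and miR-541-3p 42.2-fold, while miR-329-3p and miR-376b-5p rose 9.68-fold and 7.90-fold and miR-154-3p rose at least 79.99-fold (251 ± 135 against 0 reads). miR-204-5p rose 5.86-fold (8508 ± 1336 against 1451 ± 277), miR-128-3p 5.51-fold, miR-342-3p 3.35-fold (7512 ± 353 against 2239.8 ± 435) and miR-700-3p 4.11-fold, and miR-342-5p and miR-135b-5p, at 0 CCK reads, rose at least 46.1-fold and 29.7-fold. At 0 VIP reads were miR-3059-5p (113 ± 5.94 in CCK, at least 211-fold lower), miR-194-5p (91.6 ± 33.2, at least 171-fold), miR-1188-5p (at least 100.4-fold) and miR-540-5p (at least 94.5-fold). miR-34c-5p, with 2 reads in VIP, stood at 0.350 ± 0.495 against 224 ± 43.1 in CCK, and miR-344d-3p and miR-130a-3p fell 154-fold and 70.7-fold. miR-7a-5p fell 1.91-fold (10937 ± 1378 against 20909.7 ± 999.6), a call not made with median-ratio scaling, quantile normalization, edgeR or DESeq2.

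limma passed 91 of 305 miRNAs between VIP and CCK, 25 higher and 66 lower in VIP, and the groups did not overlap for 191. The balance moved with the scaling, whose shift was −0.82: median-ratio scaling gave 38 higher and 31 lower, quantile normalization 29 and 34, edgeR 25 and 10, and DESeq2 44 and 31. Leaving out a CCK library removed nearly all calls, with 2 without CCK replicate 1 and 1 without CCK replicate 2, against 65 without VIP replicate 1 and 52 without VIP replicate 2. Of the calls named for this pair, miR-409-5p was made in all of these settings and miR-27b-3p in all but that without CCK replicate 2. miR-3059-5p, miR-194-5p, miR-1188-5p and miR-130a-3p fell under the minimum for testing without a CCK library. The other calls named were lost without CCK replicate 1 and without CCK replicate 2. With median-ratio scaling miR-34c-5p and miR-344d-3p did not pass, and edgeR did not pass miR-342-5p, miR-135b-5p, miR-3059-5p, miR-194-5p, miR-1188-5p, miR-540-5p, miR-130a-3p, miR-27a-3p or miR-541-3p. In simulated data on 297 tested miRNAs, 2.96% of 2-fold, 25% of 4-fold and 54.0% of 16-fold changes were recovered.

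By list, VIP against CCK gave members higher, lower and not passed of 1, 5 and 16 for neuronal brain miRNAs, 0, 2 and 1 for hypothalamic and endocrine miRNAs, 3, 9 and 16 for clock-linked miRNAs, 0, 2 and 10 for activity-regulated miRNAs, 0, 1 and 0 for the miR-183, miR-96 and miR-182 sensory cluster, and 4, 11 and 26 for the miR-379 to miR-410 imprinted cluster. After these came 0, 3 and 16 for the miR-127 and miR-136 imprinted cluster, 1, 2 and 6 for the let-7 family, 2, 2 and 1 for the miR-30 family, 1, 0 and 2 for the miR-29 family, 0, 0 and 5 for the miR-17 to miR-92a and paralogue clusters, and 1, 0 and 2 for Htr2c-intron miRNAs. Final counts were 0, 0 and 2 for oligodendrocyte miRNAs, 1, 0 and 2 for microglia and leukocyte miRNAs, 1, 0 and 2 for erythrocyte miRNAs, 0, 0 and 5 for vascular miRNAs, 1, 2 and 1 for choroid plexus and ciliated-cell miRNAs, and 0, 1 and 2 for liver and gut miRNAs. Adjusted over the list alone, clock-linked miRNAs gave 4 rises and 10 falls, activity-regulated miRNAs 1 and 5, and the miR-379 to miR-410 imprinted cluster 5 and 12. No list passed camera (smallest adjusted p = 0.99 with limma's camera; adjusted p = 0.99 with an estimated correlation). Medians changed sign with median-ratio scaling for neuronal brain miRNAs (−0.09 to 0.56), clock-linked miRNAs (−0.79 to 0.03) and the miR-379 to miR-410 imprinted cluster (−0.68 to 0.07, camera direction up). The miR-30 family (−1.25), vascular miRNAs (−2.93) and choroid plexus and ciliated-cell miRNAs (−2.71) had negative medians and a camera direction of up.

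LP libraries were set against CTRL libraries at CT18 to look for miRNAs that respond to light. miR-132-3p, the best-known light-induced miRNA of the SCN (chromosome 11, 75173682 to 75173747, GRCm38), stood at 916 ± 52.3 against 809.7 ± 74 CPM (mean ± SD, n = 2 libraries per group), a log2 fold change of 0.18 ± 0.20 SE. Its cluster partner miR-212 gave 2819 ± 559 against 2433 ± 24.9 for miR-212-5p (0.20 ± 0.21) and 141 ± 32.7 against 103 ± 0 for miR-212-3p (0.43 ± 0.26). None of the 3 passed. The smallest p belonged to miR-488-3p, from an intron of Astn1 (22.2 ± 4.53 against 9.55 ± 2.47, log2 fold change 1.22 ± 0.43, limma adjusted p = 0.99). miR-337-3p (35.5 ± 4.95 against 19.5 ± 6.86), miR-411-5p (24.8 ± 5.73 against 11.9 ± 5.80), miR-377-3p (25.8 ± 2.76 against 15.8 ± 4.74) and miR-106b-3p (15.1 ± 2.62 against 8.35 ± 0.919) came next and did not pass.

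Of 317 miRNAs tested between LP and CTRL, 0 passed in limma and 1 had an unadjusted p under 0.05. edgeR passed 0, with 1 under 0.05 unadjusted, and DESeq2 passed 0, with 0 unadjusted. Groups did not overlap for 59. The 95% interval of the log2 fold change reached 0.69 to either side at the median miRNA, and its upper end reached 2.57 at most. In simulated data on 322 tested miRNAs, 20.1% of 1.5-fold, 66.8% of 2-fold and 99.7% of 4-fold changes were recovered. Each simulated run held 200 changed miRNAs, so these rates may overstate recovery where few respond. Without LP replicate 2, 21 miRNAs passed, 18 higher and 3 lower in LP replicate 1, in a model whose LP arm was 1 library, so that the spread came from the 2 CTRL libraries alone. In replicate 2, 5 of the 21 lay on the same side of CTRL. The 21 were miR-7a-5p, miR-7b-5p, let-7g-5p, miR-9-5p, miR-24-3p, miR-127-3p, miR-129-5p, miR-143-3p, miR-145a-5p, miR-148b-3p, miR-34c-5p, miR-344-3p, miR-378a-3p, miR-379-5p, miR-409-5p, miR-433-5p, miR-532-5p and miR-598-3p (higher) and miR-125a-5p, miR-150-5p and miR-423-5p (lower), named after their values were seen. miR-7a-5p stood at 3360.2 ± 1907 against 1999 ± 506 over both replicates. No member of any list passed, adjusted over all miRNAs or adjusted over the list alone, and the smallest camera adjusted p was 0.18, for neuronal brain miRNAs and the miR-379 to miR-410 imprinted cluster (limma's camera; adjusted p = 0.99 with an estimated correlation).

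**Figure D4:**
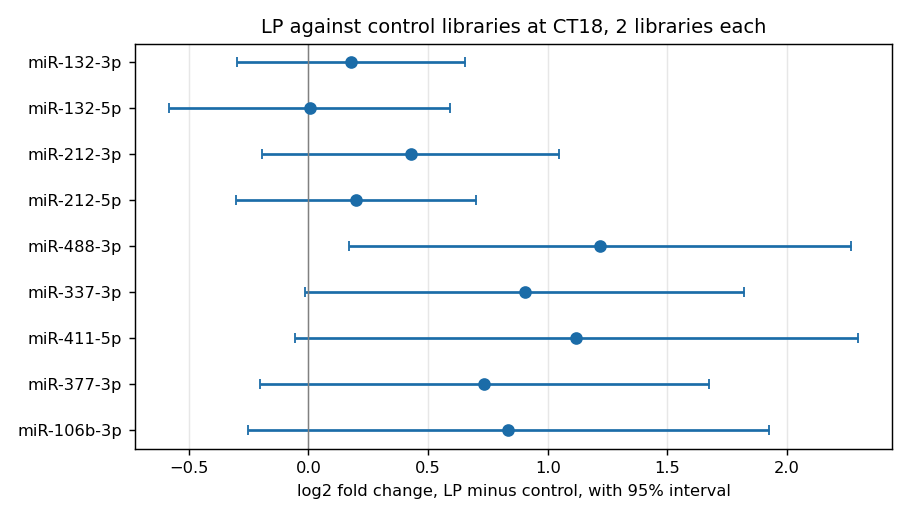
Log2 fold change, LP minus CTRL at CT18, with its 95% interval for 9 miRNAs. miR-132-3p lies at 0.18 and miR-212-3p at 0.43, with intervals that span 0, and miR-488-3p lies highest at 1.22.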

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

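Of 7468 values of named miRNAs under an alternative, 6879 (92.1%) were counted as kept, 477 no longer passed and 111 newly passed. A kept value stayed on its side of the threshold and, where either setting passed, kept its direction. Changes of direction where neither setting passed were counted as kept, and values that an alternative did not test were left out. Where a setting passed, 1 value lost its direction: let-7a-5p between hypothalamus and cortex had a log2 change of 0 after quantile normalization. In LP against CTRL and the time course 0 miRNAs passed, so being kept was close to built in (98.6% of 710 and 100% of 1169 values). Without them 89.6% of 5589 were kept. Between hypothalamus and cortex after quantile normalization, 1 of 138 shared calls, miR-99a-5p, reversed from a log2 change of 0.26 (adjusted p = 0.0102) to −0.18 (adjusted p = 0.00244). The cause of these changes was not tested. The share kept was 99.8% for SCN against cortex, 96.4% for SCN against hypothalamus, 92.8% for hypothalamus against cortex, 88.5% for AVP against VIP, 83.4% for AVP against CCK and 73.8% for VIP against CCK.

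Counts of called miRNAs moved by more than 1.5 times in these cases. SCN against cortex fell from 303 to 186 with the filter of 100 CPM, which tested 218 in place of 378. AVP against CCK (51) gave 33 with that filter (183 tested), 28 with edgeR, 26 without AVP replicate 1, and 0 without CCK replicate 1 or 2, over a range of 0 to 69 when 1 library was left out. VIP against CCK (91) gave 46 with the replicate number as a block, 35 with edgeR, 52 without VIP replicate 2, 2 without CCK replicate 1 and 1 without CCK replicate 2, over a range of 1 to 65. LP against CTRL gave 0 to 21, with 21 without LP replicate 2. The cause was not tested for edgeR and the block. Models without a CCK library tested 272 and 270 miRNAs in place of 305 and had fewer libraries. Sample titles link same-numbered replicates by the number alone, and a pairing was not excluded. Their deviations from the group means correlated at 0.07, −0.06 and 0.11 in tissue, −0.06, −0.09 and 0.12 in neurons and 0.25 at CT18. With the block, the other counts were 267, 304, 225, 81, 43 and 0 in the order SCN against hypothalamus, SCN against cortex, hypothalamus against cortex, AVP against VIP, AVP against CCK and LP against CTRL.

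With an estimated correlation 0 lists passed camera in every comparison. With the preset correlation 1 had passed in SCN against hypothalamus, 6 in SCN against cortex, 8 in hypothalamus against cortex, 1 in AVP against VIP, 1 in AVP against CCK, and 1 each for the cosine and sine terms of the time course. Among miRNAs at 100 or more in all 6 neuron libraries, 73 passed between AVP and VIP (61 shared with the full set), 41 between AVP and CCK (25 shared) and 72 between VIP and CCK (53 shared). The rhythm test passed 0 in each setting run. Alternatives planned for count tables alone did not apply.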

Other observations

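Sums of cell-type groups in tissue and neuron libraries are given as values, since these belong to separate parts and no test compared them. Microglia and leukocyte miRNAs together held 7662 ± 54.6 CPM in SCN tissue, 1253 ± 6.22 in AVP, 7699.9 ± 354 in VIP and 2459 ± 289.8 in CCK neurons (mean ± SD, n = 2). A single member, miR-342-3p, held 5471 of this in SCN tissue, 948 in AVP, 7512 in VIP and 2240 in CCK neurons, while miR-146a-5p stood at 1476 in SCN tissue and 134 in VIP and miR-150-5p at 505 and 0.850. Vascular miRNAs together held 4102 ± 42.7 CPM in SCN tissue and 11821 ± 544 in hypothalamus, 55.2 ± 48.4 in AVP, 75.8 ± 16.7 in VIP and 189.6 ± 42.5 in CCK neurons. Muscle miRNAs held 57.1 ± 16.6 in SCN tissue and 0 in both AVP libraries. Oligodendrocyte miRNAs held 1277 ± 387 in SCN tissue, 89.7 ± 63.1 in AVP, 1003 ± 349 in VIP and 686 ± 78.4 in CCK neurons. Choroid plexus and ciliated-cell miRNAs held 8826 ± 164 in SCN tissue, 8603 ± 1369 in VIP, 187 ± 146 in AVP and 1736 ± 252 in CCK neurons, of which miR-204-5p held 7478, 8508, 79 and 1451.

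The miR-127 and miR-136 imprinted cluster made up 271667 ± 5688 CPM in AVP, 231250.0 ± 47130.4 in VIP and 182174 ± 2094 in CCK neurons, 147393 ± 17917 in SCN tissue and 52301 ± 2850.3 in CTRL libraries. The let-7 family summed to 24940.2 ± 8199.7 in AVP against 104210.0 ± 7401 in VIP and 105063 ± 5412 in CCK neurons. Hypothalamic and endocrine miRNAs, mostly miR-7a-5p and miR-7b-5p, summed to 50783 ± 2251 in SCN tissue and 2881 ± 755 in CTRL libraries, and along the time course ranged from 12059 to 53013. Profiles of the time course lay 0.75 apart at 4 h, 0.77 at 12 h and 0.88 at 24 h (root mean square log2 difference, 5 pairs at 24 h), so libraries at the same clock time were no closer than neighbours.

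The tests that follow were chosen after the results were seen, except that of independent losses in AVP libraries among miRNAs of at least 50 CPM in VIP and CCK. LP replicate 1 stood apart from the other 3 CT18 libraries, and a candidate explanation is RNA of surrounding hypothalamus. Its log2 difference from the other 3 correlated with hypothalamus minus SCN at r = 0.462 across 303 miRNAs, with a slope of 0.18, where LP replicate 2 had r = −0.39 and a slope of −0.12 and the CTRL libraries r = −0.12 and −0.14 (the slopes of the 4 libraries sum to 0 by construction, so these are no separate test). The 85 hypothalamus-high miRNAs had a median of 0.41 and the 47 SCN-high miRNAs one of −0.30 (−0.24 and 0.20 in LP replicate 2). Lists higher in hypothalamus than in SCN tissue were mixed. Oligodendrocyte miRNAs summed to 1590 CPM in LP replicate 1 against 1466, 1678 and 1598 in CTRL replicates 1 and 2 and LP replicate 2. Muscle miRNAs gave 24 against 20.7, 32 and 31.5, so neither list stood out. Vascular miRNAs (1709 against 1311, 1105 and 1068) and liver and gut miRNAs (221 against 135, 151 and 141) were higher in LP replicate 1. So were neuronal brain miRNAs (90523 against 76248.5, 67065 and 68726) and hypothalamic and endocrine miRNAs (6033 against 2347, 3415.5 and 2942). Clock-linked miRNAs, the miR-30 and miR-29 families, Htr2c-intron miRNAs and the miR-379 to miR-410 imprinted cluster were highest there too, though some lists share members. Erythrocyte miRNAs were not (684.6 against 757.2, 661.8 and 854.1). The 21 miRNAs passed without LP replicate 2 had a median of 0.87 in replicate 1 and −0.14 in replicate 2, which restates the pattern, so an earlier test of the treatment by these values was dropped and a response in replicate 1 alone stays open. Hypothalamic RNA stays open too, since another source with the same miRNAs was not excluded.

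The CT18 controls differed from the ZT18 and ZT42 libraries of the time course, both SCN at 18 h. miR-24-3p stood at 44.7 ± 11.5 against 8874 ± 330 CPM, miR-22-3p at 12.3 ± 2.26 against 1921 ± 38.3, and miR-101c at 120 ± 0.990 against 0 (n = 2), and the root mean square log2 difference was 2.20. If transcription had changed, the arms of a precursor would move together: they correlated at r = 0.0169 (95% interval −0.17 to 0.21, 77 precursors), against 0.754 (0.65 to 0.84) for SCN minus cortex, which speaks against that explanation. The share of variance between clusters was 0.0169, against 0.566 for SCN minus cortex. A cluster held the mature miRNAs of neighbouring precursors, or both arms of 1 precursor. This share therefore partly repeats the arm correlation and is no separate test. Unequal capture of single sequences in library preparation may be the cause and stays open. Against SCN tissue the share for the controls was 0.294 (arms r = 0.06), and SCN tissue minus ZT18 and ZT42 had 0.470 (arms r = 0.15, −0.12 to 0.40). Levels are therefore not comparable across these parts.

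Many miRNAs were at 0 reads in both AVP libraries: among 208 of at least 10 CPM in both VIP and CCK there were 25 (12 of the 34 that passed with 0 AVP reads). Counting error at the lower of the VIP and CCK means gives 9.52e-07 (at least 15.9 reads expected for each of the 25), which speaks against too few reads by counting error alone. Differences between AVP replicates exceeded counting error, with a chi-square per degree of freedom of 85.0. That wider spread gives more zeros, and a number expected from it was not computed. There were 9 at 0 among the 168 of at least 10 CPM in all 4 VIP and CCK libraries. Among 130 at that level in VIP or CCK alone, which hold the other 22, 68 were at 0, between 82.0 from counting error at the lower mean and 2.28e-06 at the higher, so too few reads stays open there (2 earlier forms of this test, whose outcome the filter or the lower mean largely fixed, were dropped). Independent losses were tested among 148 miRNAs of at least 50 CPM in both VIP and CCK: 17 were at 0 in AVP replicate 1, 3 in replicate 2 and 3 in both (miR-329-3p, miR-672-5p and miR-1981-3p), against 0.621 from independent zeros, a ratio of 4.83 that 49 of 10000 shuffles reached. Among 190 miRNAs below that level in VIP or CCK, which hold 31 of the 34, 121 and 99 were at 0, and 90 were at 0 in both against 67.0 from independent zeros (highest of 10000 shuffles 78). These shuffles kept zeros within 3 levels of the higher of the VIP and CCK means, not of the AVP level. miRNAs low in AVP would be at 0 in both libraries even with independent losses, so this excess does not decide on such losses. A low level in AVP neurons may explain the shared zeros, and a recurring loss of particular sequences in these small libraries was not tested and stays open. Such zeros were not limited to AVP, which had 21 among the calls against VIP and 23 against CCK. VIP had 17 against CCK and 8 against AVP, and CCK had 8 against VIP and 3 against AVP.

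For the 24 h rhythm, 76 of 100 permutations of the times gave as many miRNAs at an unadjusted p under 0.05 as the real order, where the real count was 6 and the highest other 104, so chance cannot be excluded. The median of the permutations was 14 and the largest count past the adjusted threshold in any of them 33. A draw with 104, several times the real 6, points to a structure of the samples, whose cause was not tested.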
